A study of Rattus norvegicus with 35 samples.

How the data were processed

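Rats received a triazole fungicide in the feed from gestation day 6 to postnatal day 92, and liver RNA of individual animals was hybridised to Affymetrix rat genome arrays, per the labels' protocols. The treatments were myclobutanil at 500 and 2000 ppm, propiconazole at 500 and 2500 ppm and triadimefon at 500 and 1800 ppm, beside untreated controls. The series lists 35 arrays, which its design text calls biological replicates, so p-values measure the spread between animals. Whether animals of a group shared a litter is not given in the sources used here. 3 arrays that the submitters marked as left out of their final analysis (1 of myclobutanil at 2000 ppm and 2 of propiconazole at 500 ppm) hold no values and were not used here, which left 32 arrays. The extraction protocol in the labels names testis, while the sample titles and the labelling protocol name liver. The samples were taken as liver.

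The deposited values are 1 score per probe set and array, for 31099 probe sets. How the authors summarised and normalised the arrays, and the scale, log base and centring of the deposited score, are not given in the sources used here. Array medians ran from 0.00531 to 0.0585, array standard deviations from 0.701 to 1.02 and array maxima from 4.76 to 9.01, so neither the spread nor the top of the scale was equal between arrays. Among the controls, the median standard deviation of a probe set was 0.0515 where the mean score lay below 0 and 0.341 where it lay above 3. A difference of scores is therefore reported as such and is not read as a log2 fold change. The test had been designed for log2 values; it was run on the deposited scores unchanged. The number of arrays limits the precision.

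The 57 Affymetrix control probe sets were kept out of the tests, which left 31042 probe sets. The platform annotation gave 1 gene symbol to 20826 of them, several symbols to 436 and none to 9780. Entrez identifiers of 20758 of the probe sets with 1 symbol matched the rat gene table, and 0 symbols changed. 14217 genes were represented, each by its probe set with the highest mean score. Probe sets with several symbols were named by none of them. The probe set annotated to both Cyp2b2 and Cyp2b1 is reported as the Cyp2b probe set.

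All 7 groups entered 1 linear model (limma 3.58.1 in R 4.3.3, with version 1.17.8 of the package data.table), with lmFit, contrasts and eBayes at their defaults and 26.99 residual and prior degrees of freedom. The 12 comparisons were each treated group against the controls, the high against the low level of each compound, and the compounds against each other at 500 ppm. Tests were two-sided, adjusted by the Benjamini-Hochberg method within a comparison, with an adjusted p threshold of 0.05. Intervals are 95% confidence intervals from the same fit. 33 gene lists of metabolic pathways, nuclear receptor targets, stress responses and cell type markers were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the 33 lists of a comparison. The genes named per comparison with the controls were the 6 with the largest rise and the 6 with the largest fall past the threshold, up to 3 members of smallest p of each list with a member past it, and Cyp51, Cyp3a23-3a1, Cyp1a1 and Cyp2b in every case. In the other comparisons the 4 largest rises and 4 largest falls were named. Where no gene passed, the 3 of smallest p among the genes with 1 symbol are given as values. Probe sets with several symbols or none, Cyp2b included, are outside that ranking. These tests, lists, naming rules and the processing alternatives were set before the data were examined, except those described next as added.

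On simulated scores of the same group sizes and spreads, with noise independent between probe sets, the fit of triadimefon at 1800 ppm against the controls recovered 89.6% of shifts of 0.5 and 98.5% of shifts of 1 among 31042 probe sets. It made 11 false calls there, 5.42% of its calls. The shifted probe sets were drawn at random from all of them. In the real comparison the median SE of a probe set was 0.0423, against 0.263 for Cyp51, so these rates do not carry over to genes of wide spread.

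RNA integrity was read from the control probe sets for GAPDH and β-actin as the score at the 3′ end minus that at the 5′ end, averaged over both genes (the 3′–5′ difference). 9 arrays had a GAPDH difference above 0.9. The titles give each animal a number. Controls 5 to 7 and triadimefon 1800 ppm replicates 2 to 4 have numbers above 3000 and all other animals lower ones, and the numbers were treated as a possible batch. No 2 arrays of a group held the same values: the smallest mean absolute difference between such arrays was 0.0460, and their correlations across probe sets ran from 0.933 to 0.997.

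The alternatives set in advance were quantile normalisation, removal of the dimmest 40% of probe sets, the animal number series as a block, each number series alone, a fit of only the arrays of the groups compared, eBayes with trend and robust settings, the replicate number as a block, and the omission of each array in turn. For the gene lists, the mean of all probe sets of a gene was a further one. The 3′–5′ difference as a covariate, alone and with quantile normalisation, and fits without or only with the 9 arrays of high difference were added after the data had been seen. For comparisons that share the controls, 100 simulated sets of unchanged groups and 70 assignments of the controls in parts of 3 and 4 were drawn. The splits of the arrays were limited to 100 per comparison. Figures were drawn with matplotlib 3.10.9.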

Results

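The data are liver expression profiles of 32 adult rats exposed through the diet, before birth and up to postnatal day 92, to 1 of 3 triazole fungicides. There were 7 control animals, 5 at 500 and 4 at 2000 ppm myclobutanil, 3 at 500 and 4 at 2500 ppm propiconazole, and 5 at 500 and 4 at 1800 ppm triadimefon. Triazoles block the fungal lanosterol demethylase, the counterpart of rat Cyp51 in cholesterol synthesis, and can induce cytochromes P450 of the liver. All 3 compounds carry a triazole ring. Triadimefon is a ketone, myclobutanil a nitrile and propiconazole a cyclic ketal. The comparisons ask which liver transcripts differ between treated and control animals, between levels of a compound and between compounds at the same level.

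The 3′–5′ difference, taken here as a reading of RNA integrity, differed between arrays and between groups. The 3′–5′ difference of GAPDH and β-actin was 1.30 ± 0.595 in the controls (SD, n = 7), 1.21 ± 0.849 at myclobutanil 500 ppm (n = 5) and 1.49 ± 0.375 at triadimefon 1800 ppm (n = 4). It was 0.613 ± 0.0833 at myclobutanil 2000 ppm (n = 4), 0.694 ± 0.140 at propiconazole 500 ppm (n = 3), 0.609 ± 0.0672 at propiconazole 2500 ppm (n = 4) and 0.519 ± 0.0479 at triadimefon 500 ppm (n = 5). The arrays with a GAPDH difference above 0.9 were controls 4 to 7, myclobutanil 500 ppm replicates 1 and 5, and triadimefon 1800 ppm replicates 2 to 4. The first principal component held 49.7% of the variance of the arrays. Its scores followed the 3′–5′ difference over the 32 arrays (Pearson r 0.975, 0.964 without the 2 farthest arrays; Spearman rho 0.787; permutation p = 1e-05 for each, the smallest the resamples can give, adjusted 3e-05 over 6 tests). Within the 9 arrays above the GAPDH limit r was 0.938 (exact permutation p = 0.000532, adjusted 0.000798; 0.918 without the 2 farthest) and rho 0.867 (p = 0.00451, adjusted 0.00541). Within the other 23, r was 0.814 (permutation p = 0.00012, adjusted 0.00024) and rho 0.437 (p = 0.0379, adjusted 0.0379), and the relation rests on the 2 farthest arrays, without which r was 0.385. These correlations were computed after the data had been seen. The component was not set against the array SD. Myclobutanil 500 ppm replicate 1 had both the largest SD, 1.02, and the largest 3′–5′ difference, 2.45.

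**Figure D1:**
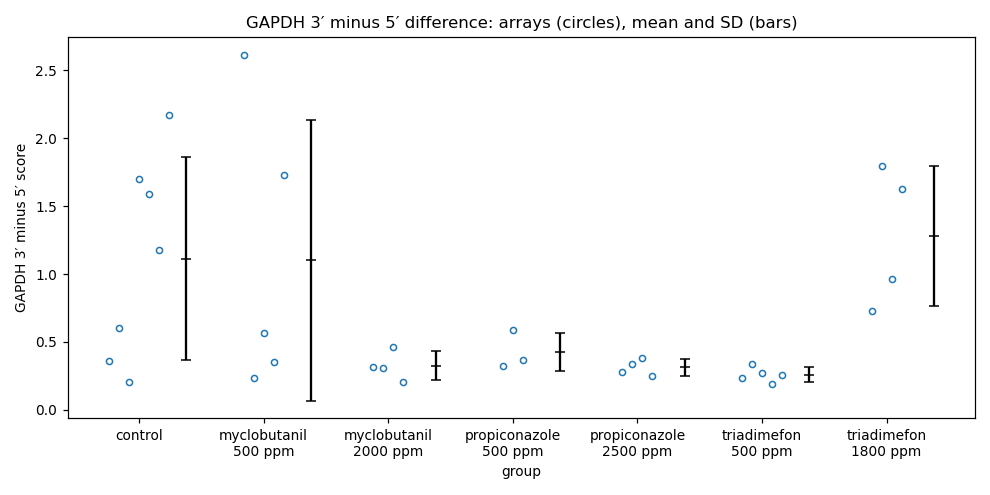
GAPDH 3′ minus 5′ score (vertical axis, deposited score units) of each array (circles) by group, with the group mean and SD as a cross-bar and bar beside them. Values run from 0.193 to 2.62, and controls, myclobutanil 500 ppm and triadimefon 1800 ppm hold all 9 arrays above 0.9.

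The probe set annotated to Cyp2b2 and Cyp2b1, phenobarbital-inducible cytochromes P450, had a mean score of 2.51 ± 0.320 in the controls (SD, n = 7). It rose by 2.93 ± 0.309 (SE) at triadimefon 1800 ppm (n = 4, adjusted p = 1.9e-06), by 2.22 ± 0.309 at propiconazole 2500 ppm (n = 4, adjusted p = 0.000863) and by 1.72 ± 0.309 at myclobutanil 2000 ppm (n = 4, adjusted p = 0.0317). At 500 ppm its differences from the controls were 1.45 ± 0.289 for myclobutanil (adjusted p = 0.734), 1.48 ± 0.340 for propiconazole (adjusted p = 0.527) and 1.49 ± 0.289 for triadimefon (adjusted p = 0.0501), and none of these passed. The 95% intervals, which are not adjusted over probe sets, were 0.86 to 2.04, 0.78 to 2.18 and 0.90 to 2.08 in the same order. All lay above 0, so a rise at 500 ppm is not excluded by the missed threshold. The rise passed under all 23 alternatives run for triadimefon 1800 ppm, all 21 for propiconazole 2500 ppm and 11 of 21 for myclobutanil 2000 ppm. In the last it was lost (adjusted p up to 0.172, difference 1.499 to 2.098 over the alternatives) with the animal number series or the replicate number as a block, among animals below 3000, without control 4, 5, 6 or 7, and without myclobutanil replicate 2, 3 or 4. At 500 ppm it passed for each compound after quantile normalisation, with or without the 3′–5′ covariate, and for triadimefon also with only the 2 groups in the fit, with trend and robust settings, and without control 1 or 3. Between the compounds at 500 ppm it differed by -0.03 for myclobutanil minus propiconazole (95% interval -0.77 to 0.70), -0.04 for myclobutanil minus triadimefon (-0.68 to 0.60) and -0.01 for propiconazole minus triadimefon (-0.75 to 0.73). The intervals of these 3 differences exclude sizes above 0.77 in either direction.

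**Figure D2:**
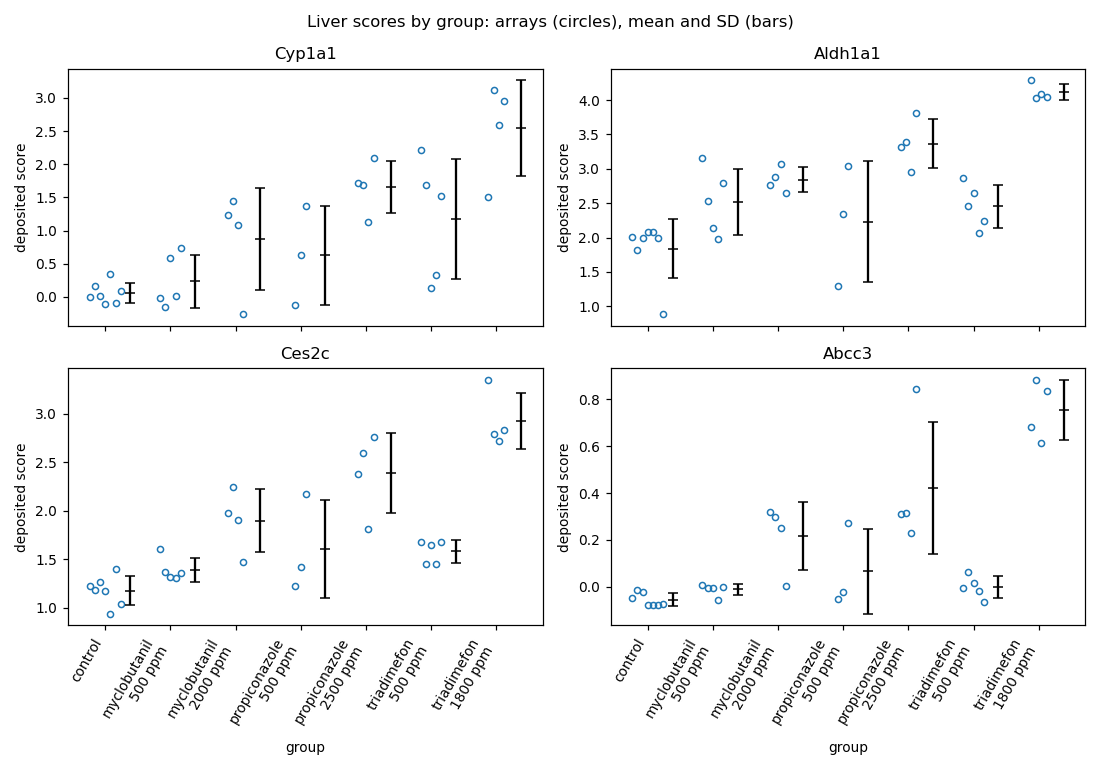
Deposited scores (vertical axis) of Cyp1a1, Aldh1a1, Ces2c and Abcc3 by group (horizontal axis), with each array as a circle and the group mean and SD as a cross-bar and bar. The 4 arrays of triadimefon 1800 ppm lie above every control array for all 4 genes, and the means there are 2.54, 4.12, 2.92 and 0.754 against 0.0586, 1.84, 1.17 and -0.0573 in the controls.

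Triadimefon at 1800 ppm (n = 4) raised genes of foreign compound metabolism and of cholesterol synthesis against the controls (n = 7). Cyp1a1, the main P450 induced through the aryl hydrocarbon receptor, rose by 2.49 ± 0.361 (SE, adjusted p = 0.000224). Aldh1a1, a retinaldehyde dehydrogenase, rose by 2.28 ± 0.255 (adjusted p = 5.5e-06) from control scores in which replicate 7 lay apart at 0.888. Ces2c, a carboxylesterase, rose by 1.75 ± 0.164 (adjusted p = 3.4e-07), and the efflux transporter Abcc3 by 0.81 ± 0.0801 (adjusted p = 8.3e-07). Ces2c and Abcc3 passed under all 23 alternatives run, Aldh1a1 and Ugt2b1 under 22, and Cyp1a1 and App under 21. Of the genes named further on, Scd and Klf6 passed under 8 of 23, Slco1a4 and Col1a2 under 10, Lcn2 and Pc under 11, and Cyp26a1 under 13 of the 22 run for it; the remaining ones passed under 16 to 22. In all, 322 probe sets were higher and 40 lower, representing 253 and 34 genes.

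Of 16 measured phase I genes associated with the receptors CAR and PXR, 5 rose over all genes tested and 10 adjusted over the list alone, with none lower in either count. Por, the reductase that passes electrons to P450s, rose by 1.15 ± 0.167, whereas Cyp3a23-3a1, a PXR target, differed by 0.98 ± 0.370 and did not pass (adjusted p = 0.260). The list ranked above other genes (camera adjusted p = 3.3e-09), a call lost at adjusted p = 0.0972 with an estimated correlation. Of 29 phase II genes, 4 rose, and adjusted over the list alone 12 rose and 2 fell. Among them were the glutathione transferases Gsta3 (1.63 ± 0.220) and Gstm4 (1.11 ± 0.183) and the glucuronosyltransferase Ugt2b1 (1.60 ± 0.230). The camera adjusted p was 0.00138, and the adjusted p was 0.613 with an estimated correlation. Of 19 transporters, 3 rose: Abcc3, Abcb1a (0.49 ± 0.0988) and Slco1a4 (1.15 ± 0.281). Adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.00138; adjusted p = 0.591 with an estimated correlation). Of 21 targets of NRF2, the regulator of the oxidant response, 3 rose, which were Gsta3, the epoxide hydrolase Ephx1 (1.24 ± 0.276) and the sulfiredoxin Srxn1 (0.40 ± 0.0793), whose other probe sets differed by -0.04 and -0.00. The lists share members: Gsta3 is also counted in the phase II list and Ephx1 in the CAR and PXR list. Adjusted over the NRF2 list alone 8 rose, and the camera adjusted p of 1.6e-05 became an adjusted p of 0.272 with an estimated correlation. Cyp1a1 was the only one of 8 AhR targets past the threshold over all genes, and 3 were adjusted over the list alone (camera adjusted p = 0.0631).

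Cholesterol synthesis genes rose together at triadimefon 1800 ppm. All 20 measured members had positive differences, with a median of 0.60, 10 passed and 17 passed adjusted over the list alone, all higher. Acat2, which makes acetoacetyl-CoA, rose by 0.77 ± 0.0795 (adjusted p = 1.5e-06). Mvd, the mevalonate diphosphate decarboxylase, rose by 0.44 ± 0.0522, Lss, the lanosterol synthase, by 0.45 ± 0.0579, and Cyp51 itself differed by 0.93 ± 0.263 without passing (adjusted p = 0.0878). The list passed with the preset correlation (camera adjusted p = 8.5e-24), with an estimated correlation (adjusted p = 0.0157) and with fry (adjusted p = 7.7e-06). Within the animals numbered above 3000 (n = 3 and 3) the median difference was 0.46 and 20 of 20 members were positive.

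**Figure D3:**
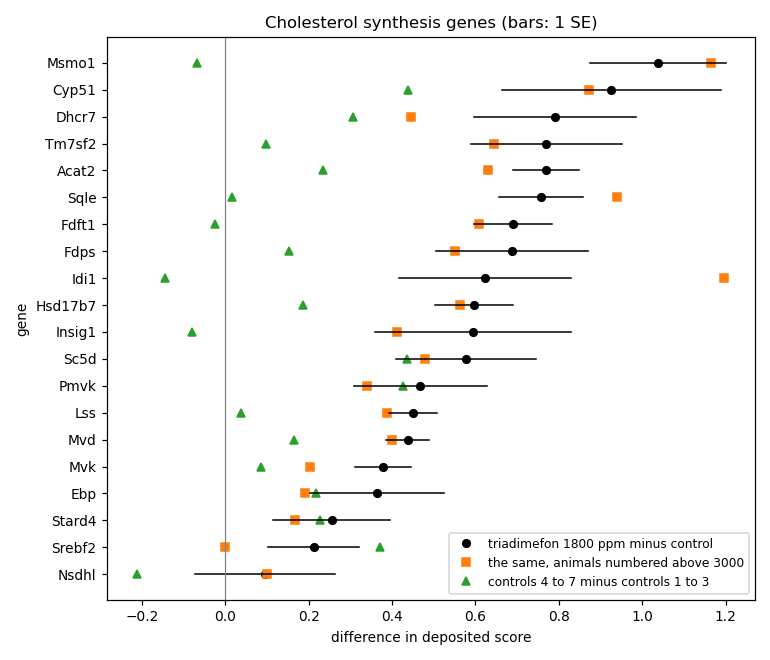
Differences in deposited score (horizontal axis) of 20 cholesterol synthesis genes (vertical axis), with triadimefon 1800 ppm minus control as black circles with bars of 1 SE, the same within animals numbered above 3000 as squares, and controls 4 to 7 minus controls 1 to 3 as triangles. The black circles are all above 0, their median is 0.60, and the medians of the squares and of the triangles are 0.46 and 0.16.

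The falls at triadimefon 1800 ppm included lipid and sugar metabolism genes. Scd, the stearoyl-CoA desaturase, fell by 1.75 ± 0.445 (SE, adjusted p = 0.0479), Apoa4, an apolipoprotein, by 1.49 ± 0.226 (adjusted p = 0.000393) and the liver pyruvate kinase Pklr by 0.84 ± 0.163. The stress-induced Nupr1 fell by 1.13 ± 0.245, the arrestin-like Arrdc3 by 1.03 ± 0.167, and pyruvate carboxylase, Pc, by 0.45 ± 0.106. Rgs3, a regulator of G protein signalling, fell by 0.90 ± 0.195; its other probe sets differed by 0.05 and 0.01, and control 7 lay apart at 0.849. Pc differed by 0.07 among the animals numbered below 3000 (n = 1 and 4) and by 0.01 without the arrays of high 3′–5′ difference (n = 1 and 3). Of 22 genes of fatty acid and triglyceride synthesis, 2 fell, Scd and Pklr, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.204). Of 15 genes of fed and fasted glucose metabolism 1 fell, Pc, and 1 rose and 1 fell adjusted over the list alone. Of 33 PPARα targets 0 passed either count in limma, where 3341 probe sets of the comparison had an unadjusted p under 0.05. They ranked below other genes (camera adjusted p = 0.0392; adjusted p = 0.687 with an estimated correlation) although their median difference was 0.02. The ranking turned, without passing, among the animals below 3000 (median 0.237) and without the arrays of high 3′–5′ difference (median 0.294). Both fits rest on the same single treated array, replicate 1.

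Single members of other lists passed at triadimefon 1800 ppm. The amyloid precursor gene App rose by 1.28 ± 0.156, its other probe sets differing by 0.99 and 0.14, and Gadd45b, a growth arrest gene and 1 of 12 in its list, by 0.49 ± 0.0560. In steroid hormone metabolism 2 of 24 rose, Hsd17b7 (0.60 ± 0.0939), which also acts in cholesterol synthesis, and Srd5a3 (0.19 ± 0.0430). In retinoid metabolism 2 of 20 rose, Aldh1a1 and the retinoic acid hydroxylase Cyp26a1 (0.22 ± 0.0515). The acute phase genes Lbp (0.77 ± 0.159) and Lcn2 (0.24 ± 0.0563) were 2 of 17, the interferon gene Oas1a (0.76 ± 0.143, replicate 3 apart at 0.640) 1 of 15 and the early gene Klf6 (0.33 ± 0.0823) 1 of 15. Interferon genes (5 higher adjusted over the list alone) and cell cycle genes (1 higher) ranked above other genes (camera adjusted p = 0.00497 and 0.0239; adjusted p = 0.613 and 0.670 with an estimated correlation). Female-biased liver genes, median 0.02 and mean -0.07, and genes of the unfolded protein response, median 0.01 and mean -0.02, ranked below (camera adjusted p = 0.0230 and 0.0216; adjusted p = 0.272 and 0.613 with an estimated correlation). Of 16 Kupffer cell markers none passed over all genes and 12 were higher adjusted over the list alone, with a median difference of 0.35 (camera adjusted p = 3.2e-06; adjusted p = 0.272 with an estimated correlation). Col1a2, a stellate cell collagen, rose by 0.31 ± 0.0782, 1 of 18 in its list, and Epcam, a biliary marker, by 0.72 ± 0.116, 1 of 11. Hepatocyte markers (16 measured) had 0 members past the threshold in limma and a median difference of 0.31, which was -0.05 after quantile normalisation.

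The count at triadimefon 1800 ppm depended on which animals were used. It was 13 within the animals numbered above 3000 (n = 3 and 3), 2461 within those below (n = 1 and 4), 306 with the number series as a block and 67 with only the arrays of the 2 groups in the fit. With the 3′–5′ difference as a covariate it was 604, without the arrays of high difference 5495 (n = 1 and 3), with only those arrays 43 (n = 3 and 4), and after quantile normalisation 305 higher and 127 lower.

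Propiconazole at 2500 ppm (n = 4) raised 41 probe sets and lowered 38 against the controls (n = 7), representing 29 genes each way. Aldh1a1 rose by 1.53 ± 0.255 (SE, adjusted p = 0.00701), Ugt2b1 by 1.25 ± 0.230 (adjusted p = 0.0161) and Ces2c by 1.21 ± 0.164 (adjusted p = 0.000863). Cyp4a8, a fatty acid hydroxylase of the PPARα list, rose by 1.03 ± 0.191, the lipid droplet protein Cidea by 0.86 ± 0.157 with replicate 1 apart at 2.01, and the glucuronosyltransferase Ugt2a1 by 0.52 ± 0.102. Fabp5, a fatty acid binding protein, fell by 0.79 ± 0.163, the phosphatase-like Mtmr7 by 0.73 ± 0.155, Lrtm2 by 0.73 ± 0.154, Rprm, a cell cycle arrest gene, by 0.52 ± 0.113, Ccdc126 by 0.43 ± 0.0875 and Elapor1 by 0.41 ± 0.0810. All 4 treated arrays lay beyond the range of the controls for each of these genes. Cyp1a1 differed by 1.60 ± 0.361, above every control in 4 of 4 arrays, without passing (adjusted p = 0.0523), Cyp51 by -0.05 ± 0.263 and Cyp3a23-3a1 by 0.12 ± 0.370.

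By group, 2 of 16 CAR and PXR phase I genes rose at propiconazole 2500 ppm, Ces2c and Aldh1a1, and 7 rose adjusted over the list alone. The camera adjusted p was 2.3e-12, and the adjusted p was 0.0259 with an estimated correlation. Of 8 AhR targets Ahr, the receptor itself, rose by 0.47 ± 0.104, with replicate 3 apart at 0.610 and its other probe set at -0.03, and 2 rose adjusted over the list alone (camera adjusted p = 0.000494; adjusted p = 0.0259 with an estimated correlation). Of 29 phase II genes 2 rose, Ugt2b1 and the glutathione transferase Gstm3 (0.51 ± 0.101), and 5 adjusted over the list alone (camera adjusted p = 6.6e-08; adjusted p = 0.295 with an estimated correlation). Of 19 transporters 1 rose, Abcc3 (0.48 ± 0.0801, replicate 4 apart at 0.843), and 3 adjusted over the list alone (camera adjusted p = 0.000519; adjusted p = 0.657 with an estimated correlation). Of 21 NRF2 targets 1 rose, the glutathione reductase Gsr (0.44 ± 0.0968), while 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.9e-08; adjusted p = 0.126 with an estimated correlation). Of 33 PPARα targets 1 rose, Cyp4a8, and adjusted over the list alone 3 rose and 2 fell. Cyp7b1, a hydroxylase of bile acid synthesis, fell by 0.27 ± 0.0540, 1 of 16 in its list. Its mean scores were low, -0.380 against -0.112 in the controls. Of 22 fatty acid synthesis genes none passed over all genes, and adjusted over the list alone 1 rose and 10 fell (camera adjusted p = 0.146). Of 20 cholesterol synthesis genes none passed either count in limma, and their median difference was -0.01.

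Ces2c passed under all 21 alternatives run for propiconazole 2500 ppm and Aldh1a1 and Abcc3 under 17. Cidea passed under 16, Ugt2b1 under 15, Cyp4a8 under 14, Ugt2a1 under 10, and Ccdc126 and Elapor1 under 9. Fabp5 and Gsr passed under 6, Mtmr7, Lrtm2, Rprm, Gstm3 and Ahr under 7, and Cyp7b1 under 7 of the 20 run for it. The count of 79 was 39 with only the 2 groups in the fit, 25 with the 3′–5′ difference as a covariate, 21 without the arrays of high difference, 18 with the number series as a block, 9 among animals below 3000, 138 with trend and robust settings and 311 after quantile normalisation. Of the 25 with the covariate, 21 were higher and 4 lower. Leaving out controls 1 to 7 in turn gave 984, 140, 1030, 28, 40, 32 and 39, and leaving out propiconazole replicates 1 to 4 gave 10, 28, 49 and 8.

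Myclobutanil at 2000 ppm (n = 4) lowered 17 probe sets and raised 3 against the controls (n = 7). Apart from the Cyp2b probe set, Birc7, an apoptosis inhibitor, rose by 0.21 ± 0.0342 (SE, adjusted p = 0.0236), with control 3 apart at 0.182. The corepressor Tle1 fell by 0.59 ± 0.110 (adjusted p = 0.0327), the thioredoxin-related Tmx4 by 0.49 ± 0.0936, Ccdc126 by 0.47 ± 0.0875, the nuclear pore gene Ahctf1 by 0.39 ± 0.0756, Champ1 by 0.35 ± 0.0632 and the splicing regulator Mbnl3 by 0.35 ± 0.0646, each below every control in 4 of 4 arrays. Cyp1a1 differed by 0.82 ± 0.361 (adjusted p = 0.173), Cyp51 by -0.36 ± 0.263 (adjusted p = 0.387) and Cyp3a23-3a1 by -0.16 ± 0.370 (adjusted p = 0.809). Of 16 CAR and PXR phase I genes none passed over all genes and 3 were higher adjusted over the list alone (camera adjusted p = 2.2e-05; adjusted p = 0.442 with an estimated correlation). The phase II list ranked above other genes although its median difference was -0.00 (camera adjusted p = 0.00934; adjusted p = 0.989 with an estimated correlation), and so did AhR targets, with 2 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00934; adjusted p = 0.206 with an estimated correlation). Retinoid genes did so with a negative median, -0.04, and NRF2 targets with a median of -0.01 and a positive mean, 0.07 (camera adjusted p = 0.0355 and 0.00934; both adjusted p = 0.989 with an estimated correlation). Testis markers, 14 of 19 positive, also ranked higher (camera adjusted p = 0.000882; adjusted p = 0.568 with an estimated correlation). Replicate 5 stood apart in germ-cell transcripts, and without it the median of these markers was -0.00 and the camera adjusted p 0.0440.

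Of the 21 alternatives run for myclobutanil 2000 ppm, the 7 genes named here and the Cyp2b probe set passed under 6 (Tmx4) to 11 (Birc7 and the Cyp2b probe set). The count of 20 was 2 with the 3′–5′ difference as a covariate, 2 with the number series as a block, 0 with limma among animals below 3000 (2961 at unadjusted p under 0.05), 120 with trend and robust settings and 79 after quantile normalisation, then 43 higher and 36 lower. The 2 with the 3′–5′ covariate were both higher, so the reported balance towards lower probe sets was not kept there. Leaving out controls 1 to 7 in turn gave 332, 38, 3013, 0, 7, 6 and 9, and leaving out myclobutanil replicates 2 to 5 gave 0, 0, 0 and 9, the 0 counts again with limma, where 7518 probe sets of the full comparison had an unadjusted p under 0.05.

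At 500 ppm few or no genes passed. Triadimefon (n = 5) lowered 3 probe sets and raised 0 in limma (9108 at unadjusted p under 0.05), among them Elapor1, which fell by 0.46 ± 0.0757 (SE, adjusted p = 0.0299, below all controls in 5 of 5 arrays), and Tram1l1, which fell by 0.19 ± 0.0336 (adjusted p = 0.0373). Tram1l1 was dim: its means, -0.476 with triadimefon and -0.281 in the controls, lay below -0.193, the lower quartile of all probe set means. Cyp1a1 differed by 1.12 ± 0.337 (adjusted p = 0.0759), Cyp51 by -0.13 ± 0.246 (adjusted p = 0.731) and Cyp3a23-3a1 by -0.25 ± 0.346 (adjusted p = 0.639). Of 8 AhR targets 2 were higher adjusted over the list alone, and the list ranked above other genes with the preset (camera adjusted p = 1.4e-05) and with an estimated correlation (adjusted p = 0.00339). The CAR and PXR list (1 of 16 higher adjusted over the list alone; camera adjusted p = 2.4e-06) and the cholesterol list (2 of 20; 5.7e-05) lost the call with an estimated correlation, at adjusted p = 0.286 and 0.757. Phase II genes ranked higher with a negative median, -0.11 (camera adjusted p = 0.000595), as did testis markers with a median of -0.00 and a mean of 0.04 (0.0109), NRF2 targets (0.00853) and interferon genes with a median of 0.02 and a mean of -0.02 (0.00853), and each had an adjusted p of 0.757 with an estimated correlation. The ranking of the testis markers turned, without passing, with the 3′–5′ difference as a covariate. Elapor1 passed under 8 alternatives and not under 14, and Tram1l1 under 7 and not under 14. The count of 3 was 0 with limma with the 3′–5′ difference as a covariate, 33 with only the 2 groups in the fit, 96 with trend and robust settings and 41 after quantile normalisation, then 20 higher and 21 lower. Leaving out controls 1 to 7 in turn gave 3746, 17, 4464, 0, 0, 1 and 4, and leaving out triadimefon replicates 1 to 5 gave 1, 0, 0, 0 and 0.

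Myclobutanil at 500 ppm (n = 5) gave 0 probe sets past the threshold in limma and 1281 at an unadjusted p under 0.05. Among genes with 1 symbol, the smallest p values were those of Hivep1 (-0.18 ± 0.0378), Ccdc126 (-0.37 ± 0.0817) and Tle1 (-0.47 ± 0.103), all at an adjusted p of 0.734. The Cyp2b probe set had a smaller unadjusted p in limma than each of them, 2.92e-05 (adjusted p = 0.734). Cyp1a1 differed by 0.18 ± 0.337, Cyp51 by 0.03 ± 0.246 and Cyp3a23-3a1 by 0.31 ± 0.346, with replicate 1 apart at 6.82, each at an adjusted p of 0.9996. Without that replicate Cyp3a23-3a1 differed by -0.24 and Cyp51 by -0.36. All 16 CAR and PXR phase I genes had positive differences, with a median of 0.24, and none passed even adjusted over the list alone (camera adjusted p = 4.2e-05; adjusted p = 0.431 with an estimated correlation). With 1 array left out in turn, that median ran from 0.0083 to 0.351 and the camera adjusted p rose to as much as 0.0383. Phase II genes and retinoid genes ranked higher, and genes of the unfolded protein response lower (camera adjusted p = 0.0328 each; 0.941, 0.837 and 0.837 as adjusted p with an estimated correlation). The ranking of the phase II genes turned without the arrays of high 3′–5′ difference (median -0.11, not past the threshold). Immediate early genes ranked lower too (camera adjusted p = 0.0494; adjusted p = 0.837 with an estimated correlation). Testis markers, 15 of 19 positive, ranked higher (camera adjusted p = 0.00028; adjusted p = 0.431 with an estimated correlation), a call lost without replicate 2 (camera adjusted p = 0.115). Without myclobutanil replicate 1, the array with the largest 3′–5′ difference, 2 probe sets passed, and 8 passed without the arrays of high difference (n = 3 and 3).

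Propiconazole at 500 ppm (n = 3) gave 0 probe sets past the threshold in limma and 2866 at an unadjusted p under 0.05. Among genes with 1 symbol, the smallest p values were those of the transporter Slc16a6 (0.20 ± 0.0454), the adhesion receptor Adgrg6 (-0.12 ± 0.0272) and Hoxa5 (-0.09 ± 0.0218), at an adjusted p of 0.527. Hoxa5 was dim, with means of -0.315 and, in the controls, -0.220. The Cyp2b probe set had a smaller unadjusted p in limma than Adgrg6 and Hoxa5, 0.000172 (adjusted p = 0.527). Cyp1a1 differed by 0.57 ± 0.398 (adjusted p = 0.600), Cyp51 by -0.21 ± 0.290 (adjusted p = 0.779) and Cyp3a23-3a1 by -0.11 ± 0.408 (adjusted p = 0.932). Of 16 CAR and PXR genes 2 were higher adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.401 with an estimated correlation). The phase II list (camera adjusted p = 0.0435) and the AhR list (0.0304) lost the call with an estimated correlation, at adjusted p = 0.999 and 0.245. With the 3′–5′ difference as a covariate the negative differences of Cyp51 and Cyp3a23-3a1 from the controls, none of which passed, became positive at myclobutanil 2000 ppm (0.10 and 0.46), propiconazole 500 ppm (0.19 and 0.44) and triadimefon 500 ppm (0.40 and 0.46), and that of Cyp51 at propiconazole 2500 ppm became 0.41. Leaving out control 1 gave 1 probe set past the threshold.

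Between the levels of triadimefon, 1800 ppm (n = 4) against 500 ppm (n = 5), 6927 probe sets were higher and 763 lower, representing 4575 and 567 genes. Aldh1a1 rose by 1.66 ± 0.273 (SE, adjusted p = 0.00096), Cyp1a1 by 1.37 ± 0.387, Ces2c by 1.34 ± 0.175 (adjusted p = 0.000103) and App by 1.27 ± 0.166, with other App probe sets at 0.66 and -0.29. A1cf, which takes part in editing of apolipoprotein B mRNA, fell by 0.97 ± 0.279, Nupr1 by 0.88 ± 0.262, the acyl-CoA dehydrogenase Acadsb by 0.88 ± 0.232 and Apoa4 by 0.75 ± 0.242. Cyp51 rose by 1.06 ± 0.282 (adjusted p = 0.0125), Cyp3a23-3a1 by 1.23 ± 0.397 (adjusted p = 0.0282) and the Cyp2b probe set by 1.44 ± 0.331 (adjusted p = 0.0063). Of 20 cholesterol synthesis genes 17 rose, 18 adjusted over the list alone; 13 of 24 cell cycle genes rose, 16 adjusted over the list alone; and 11 of 16 Kupffer cell markers rose, 13 adjusted over the list alone. The camera adjusted p values were 1.4e-05, 0.0499 and 0.0499, and all 3 became an adjusted p of 0.974 with an estimated correlation. PPARα targets ranked below other genes with a positive median of 0.08 (camera adjusted p = 0.00923), as did testis markers (0.00421), both at an adjusted p of 0.974 with an estimated correlation. The ranking of the PPARα targets turned, without passing, among animals below 3000 and without the arrays of high 3′–5′ difference, with a median of 0.369 in both. Both fits hold the same arrays of these groups, with replicate 1 as the only one at 1800 ppm, so they count as 1 alternative.

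The 3′–5′ difference was 1.49 at triadimefon 1800 ppm and 0.519 at 500 ppm. The count of 7690 was 88 with that difference as a covariate, 763 with the number series as a block, 4132 among animals below 3000 (n = 1 and 5), 5113 without the dimmest probe sets, and 3001 after quantile normalisation, then 1661 higher and 1340 lower. It was 4919 without triadimefon 1800 ppm replicate 2, 4442 without replicate 4 and 5094 without triadimefon 500 ppm replicate 5. Ces2c and App passed under all 19 alternatives run, Aldh1a1 under 18, the Cyp2b probe set under 16, Acadsb under 14, A1cf and Nupr1 under 13, and Cyp1a1 and Apoa4 under 10. The differences ran over the alternatives from 0.335 to 1.71 for Cyp1a1, -1.12 to -0.23 for A1cf, -0.98 to -0.26 for Acadsb, -1.26 to -0.16 for Apoa4, -1.18 to -0.75 for Nupr1 and 0.66 to 2.28 for the Cyp2b probe set. The calls of all 6 were lost with the 3′–5′ difference as a covariate.

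Between 2000 and 500 ppm myclobutanil 0 probe sets passed in limma (3404 at unadjusted p under 0.05, smallest adjusted p 0.447), the smallest p values being those of Muc4 (-0.10 ± 0.0255), Or5ak25 (-0.12 ± 0.0326) and the hexokinase Hk2 (-0.12 ± 0.0318). Muc4 and Or5ak25 were dim, with means of -0.367 and -0.435 at 2000 ppm and -0.271 and -0.312 at 500 ppm. The Cyp2b probe set differed by 0.27 (95% interval -0.41 to 0.95), Cyp1a1 by 0.64 (-0.15 to 1.43) and Ces2c by 0.51 (0.15 to 0.87). AhR and NRF2 targets ranked higher (camera adjusted p = 0.0125 each), as did transporters with a negative median, -0.06 (0.0352), and their adjusted p values were 0.130, 0.966 and 0.966 with an estimated correlation. Between 2500 and 500 ppm propiconazole 0 passed in limma (365 at unadjusted p under 0.05, smallest adjusted p 1), the smallest p values being those of Adgrg6 (0.12 ± 0.0301), Cidea (0.77 ± 0.192) and Anxa7 (0.46 ± 0.116). The Cyp2b probe set differed by 0.74 (-0.03 to 1.51), Ces2c by 0.78 (0.37 to 1.19) and Aldh1a1 by 1.14 (0.50 to 1.78). Of the 33 lists 8 ranked higher and 2 lower, led by NRF2 targets (camera adjusted p = 2.7e-10; adjusted p = 0.157 with an estimated correlation) and phase II genes (1.9e-06; adjusted p = 0.446 with an estimated correlation), and none passed with an estimated correlation.

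At the matched level of 500 ppm, 0 probe sets passed in limma between myclobutanil and propiconazole (1332 at unadjusted p under 0.05), 0 between myclobutanil and triadimefon (5934) and 0 between propiconazole and triadimefon (772). Cyp1a1 differed by -0.39 between myclobutanil and propiconazole (95% interval -1.25 to 0.47), by -0.94 between myclobutanil and triadimefon (-1.69 to -0.20, adjusted p = 0.239) and by -0.55 between propiconazole and triadimefon (-1.42 to 0.31). Ces2c differed by -0.22 (-0.61 to 0.17), -0.19 (-0.53 to 0.15) and 0.02 (-0.37 to 0.42), and Cyp51 by 0.24 (-0.39 to 0.87), 0.16 (-0.38 to 0.70) and -0.08 (-0.71 to 0.55), in the same order. AhR targets, 0 of 8 positive, ranked lower with myclobutanil than with triadimefon (camera adjusted p = 1.8e-05; adjusted p = 0.0038 with an estimated correlation). Cholesterol synthesis genes ranked lower with myclobutanil (camera adjusted p = 2.4e-08) and with propiconazole (1.4e-08) than with triadimefon, at adjusted p = 0.420 and 0.391 with an estimated correlation. The smallest p values were those of Adgrg6 (0.11 ± 0.0288), Hs3st5 (0.10 ± 0.0264) and Hoxd11 (0.13 ± 0.0324) for myclobutanil minus propiconazole, Defb1 (0.19 ± 0.0386), Neu3 (0.14 ± 0.0296) and Lamb3 (0.20 ± 0.0430) for myclobutanil minus triadimefon, and St3gal5 (0.18 ± 0.0468), Lgals2 (-0.16 ± 0.0441) and Tigd5 (-0.08 ± 0.0217) for propiconazole minus triadimefon. Hs3st5 was dim, with means of -0.256 with myclobutanil and -0.359 with propiconazole.

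The high levels differ between compounds, so their values stand side by side without a test of the compounds. Against the controls Ces2c differed by 0.72 at 2000 ppm myclobutanil (95% interval 0.39 to 1.06, adjusted p = 0.05798), 1.21 at 2500 ppm propiconazole and 1.75 at 1800 ppm triadimefon, passing in the last 2. Cyp1a1 differed by 0.82, 1.60 and 2.49 at 2000 ppm myclobutanil, 2500 ppm propiconazole and 1800 ppm triadimefon, passing in the last. 8 probe sets passed in all 3 high groups: the Cyp2b probe set, an App probe set, Birc7, Ccdc126, Adgrv1 and 3 without a name; Adgrv1 and the App probe set lie outside the naming rule and were chosen after their values were seen. Myclobutanil 2000 ppm and propiconazole 2500 ppm shared 3 higher and 9 lower probe sets, where independent lists would share 0.00396 and 0.0208. Propiconazole 2500 ppm and triadimefon 1800 ppm shared 17 higher and 11 lower, against 0.425 and 0.049 for independent lists. Myclobutanil 2000 ppm and triadimefon 1800 ppm shared 3 higher and 6 lower, against 0.0311 and 0.0219. These figures leave out the shared controls, and simulated unchanged groups against the same controls shared a median of 0. With separate control animals for each comparison, 3 or 4 each, the first pair shared a median of 0 (range 0 to 9, against 12) and the second a median of 7 (2 to 61, against 28). The last pair shared a median of 0 (0 to 34, against 9).

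Across probe sets, which are not independent replicates, the differences from control correlated at 0.910 between myclobutanil 2000 ppm and propiconazole 2500 ppm. Simulated unchanged groups gave a median of 0.493, and separate control animals for each comparison gave a median of 0.733. The covariance was 0.0167 against a simulated mean of 0.00315. Both groups had a lower mean 3′–5′ difference than the controls (0.613 and 0.609 against 1.30), as had propiconazole and triadimefon at 500 ppm (0.694 and 0.519). Triadimefon 1800 ppm had a higher one (1.49). A shared response to the compounds and the shared shift of the 3′–5′ difference are therefore not separated here. Propiconazole and triadimefon at 500 ppm correlated at 0.859 (simulated 0.353, separate controls 0.676), with a covariance of 0.0133 against 0.00263. The correlation of propiconazole 2500 ppm with triadimefon 1800 ppm was 0.090 (simulated 0.420, separate controls -0.0027), and that of myclobutanil 2000 ppm with triadimefon 1800 ppm -0.0166 (simulated 0.363, separate controls -0.0843). At 500 ppm myclobutanil correlated at 0.479 with propiconazole (simulated 0.342, separate controls 0.217) and at 0.356 with triadimefon (simulated 0.481, separate controls 0.176).

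Germ-cell transcripts were measured on most liver arrays. Prm1 lay below 0 on controls 5 and 6 and on triadimefon 1800 ppm replicates 1, 3 and 4. On every other array it was 0.526 or higher. Prm1, the sperm protamine, ranged from -0.329 to 3.15 over the 32 arrays, the transition protein Tnp1 from -0.343 to 1.44 and the sperm tail gene Odf1 from -0.142 to 1.34. The mean of 7 germ-cell genes was 1.01 on myclobutanil 2000 ppm replicate 5 and 0.902 on triadimefon 1800 ppm replicate 2, where the other arrays of these groups lay between 0.0672 and 0.221 and between -0.241 and -0.218. In other groups this mean was 0.929 and 0.741 on myclobutanil 500 ppm replicates 2 and 5, and 0.752 on triadimefon 500 ppm replicate 3. These 7 genes were averaged after the data had been seen.

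**Figure D4:**
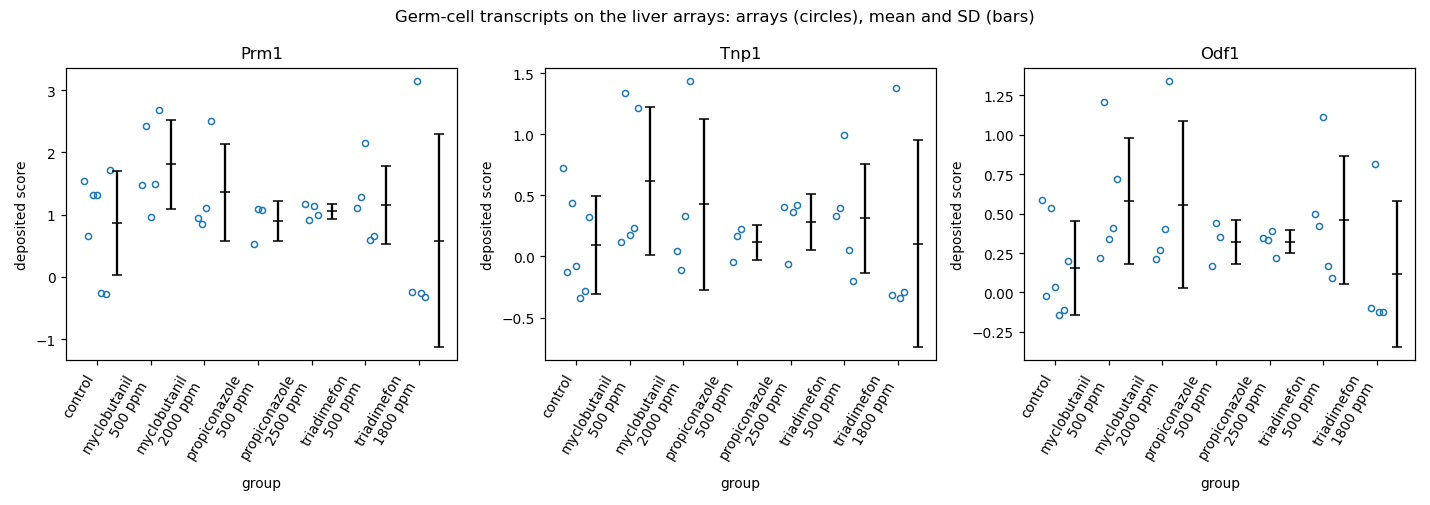
Deposited scores (vertical axis) of Prm1, Tnp1 and Odf1 by group (horizontal axis), with each array as a circle and the group mean and SD as a cross-bar and bar. Arrays of 1 group spread widely, with Prm1 at 3.15 on 1 triadimefon 1800 ppm array and below 0 on the other 3.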

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

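The tests of the germ-cell transcripts against the groups and against RNA integrity were chosen after the result had been seen, and the test on a second germ-cell list before. In 158 groups of 4 to 7 arrays, the highest or lowest value was tested for its gap to the nearest other value, and 10 stood apart, where chance alone gives about 5% of groups.

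Among the named genes, single animals stood apart from the others of their group. Cyp3a23-3a1 was 6.82 in myclobutanil 500 ppm replicate 1 (others 3.724 to 4.604). Cidea was 2.01 in propiconazole 2500 ppm replicate 1 (others 1.23 to 1.35), Abcc3 was 0.843 in replicate 4 (0.227 to 0.314) and Ahr 0.610 in replicate 3 (0.405 to 0.431). Oas1a was 0.640 in triadimefon 1800 ppm replicate 3 (others 1.17 to 1.27). Among the controls Birc7 was 0.182 in replicate 3 (others -0.0164 to 0.0496), and in replicate 7 Aldh1a1 was 0.888 (others 1.83 to 2.09) and Rgs3 0.849 (1.55 to 2.05). Explanations of these single values were not tested.

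The control probe sets, which entered no comparison, differed between arrays. On myclobutanil 500 ppm replicate 1 the 3′–5′ difference of GAPDH was 2.62, where the controls ran from 0.203 to 2.17, and that of β-actin was 2.29, where the controls ran from 0.797 to 2.07.

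The mean of 7 germ-cell genes was 1.01 in myclobutanil 2000 ppm replicate 5 (others 0.0672 to 0.221) and 0.902 in triadimefon 1800 ppm replicate 2 (others -0.241 to -0.218). Of this mean's variance 98.8% was left by a line on the 3′–5′ difference (interval 74.75 to 99.99), which argues against a loss of RNA integrity as the cause; permutation tests run first gave Pearson r -0.110 (p = 0.554; -0.158 without the 2 farthest arrays) and Spearman rho -0.255 (p = 0.161). The treatment group cannot be told apart as a cause: 82.0% of the variance lay within groups (interval 35.7 to 90.3), and a permutation test of the groups gave p = 0.4996. Testis RNA in the liver samples stays open as a candidate explanation, since 20 measured genes of a second germ-cell list had a median Spearman correlation of 0.536 with Prm1, above the upper percentile of 0.114 for random lists, while 8 testis somatic genes had mean scores from -0.281 (Cyp11a1) to 0.134 (Cyp17a1) and Spearman correlations with Prm1 from -0.290 (Amh) to 0.224 (Insl3). The extraction protocol names testis, and where such RNA could have entered was not tested. The animal number series was not tested against the mean of 7 germ-cell genes either. Above 3000 that mean ran from -0.241 to -0.201 on controls 5 and 6 and triadimefon 1800 ppm replicates 3 and 4. It was 0.281 on control 7 and 0.902 on triadimefon replicate 2. Below 3000 it was -0.218 on triadimefon 1800 ppm replicate 1 and -0.0280 or higher on all others.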

How the results depend on the processing

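The 3′–5′ covariate, alone or with quantile normalisation, and the fits without or only with arrays of high 3′–5′ difference were chosen after seeing the data. Counts of probe sets past the threshold within 1.5 times the reported ones are not listed. Zero counts are from limma, and 2961, 2769, 4135, 1306 and 2457 probe sets had an unadjusted p under 0.05 for the 5 counts of 0 in the order given. Except where named, the cause was not tested. Quantile normalisation gave 1 at myclobutanil 500 ppm, 79 at 2000 ppm, 2 at propiconazole 500 ppm, 311 at 2500 ppm, 41 at triadimefon 500 ppm and 3001 between the triadimefon levels. Without the dimmest 40% of probe sets, fewer were tested, and triadimefon 500 ppm gave 1 and its levels 5113. With the animal number series as a block, myclobutanil 2000 ppm gave 2, propiconazole 2500 ppm 18, triadimefon 500 ppm 1 and its levels 763. Only animals numbered below 3000 gave 0 at myclobutanil 2000 ppm, 9 at propiconazole 2500 ppm, 0 at triadimefon 500 ppm, and, with 1 treated array at 1800 ppm that is assumed to vary like the other groups, 2461 there and 4132 between its levels; only those above gave 13 at triadimefon 1800 ppm. With only the arrays of the 2 groups, propiconazole 2500 ppm gave 39, triadimefon 500 ppm 33, triadimefon 1800 ppm 67 and myclobutanil against triadimefon at 500 ppm 2. eBayes with trend and robust settings gave 120 at myclobutanil 2000 ppm, 138 at propiconazole 2500 ppm and 96 at triadimefon 500 ppm. The replicate block gave 0 at myclobutanil 2000 ppm and 10 at propiconazole 2500 ppm; the numbers do not pair the arrays (24 of 76 pairs over 0.1, median r -0.0101). The covariate gave 2 at myclobutanil 2000 ppm, 25 at propiconazole 2500 ppm, 0 at triadimefon 500 ppm, 604 at 1800 ppm, the reported 362 among them, and 88 between its levels. With quantile normalisation too, myclobutanil gave 1 at 500 and 9 at 2000 ppm, propiconazole 1 at 500 ppm, triadimefon 660 at 1800 ppm and 48 between its levels. Without arrays of high difference, myclobutanil 500 ppm gave 8, propiconazole 1 at 500 and 21 at 2500 ppm, triadimefon 0 at 500 and 5495 at 1800 ppm (1 treated array); only those arrays gave 43 at 1800 ppm. Leaving out 1 array gave 0 to 2 at myclobutanil 500 ppm, 0 to 3013 at 2000 ppm, 0 to 1 at propiconazole 500 ppm, 8 to 1030 at 2500 ppm, 0 to 4464 at triadimefon 500 ppm, 254 (without control 1 or triadimefon replicate 4) to 440 (without control 5) at 1800 ppm and 4442 to 7579 (without 1800 ppm replicate 1) between its levels; the report names the arrays behind the other ranges.

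Directions that reversed are given as differences, or list medians where the ranking against other genes turned. Pc at triadimefon 1800 ppm was 0.0670 among animals below 3000 and 0.0103 without arrays of high difference. After quantile normalisation hepatocyte markers were -0.0509 at triadimefon 1800 ppm and -0.0716 between its levels, and acute phase genes -0.0512 between myclobutanil and triadimefon at 500 ppm. Among animals below 3000 PPARα targets were 0.237 at triadimefon 1800 ppm and 0.369 between its levels. With the covariate, hepatocyte markers were 0.133 and testis markers -0.0140 at triadimefon 500 ppm, and testis markers 0.0609 between myclobutanil and triadimefon at 500 ppm. With quantile normalisation and covariate, acute phase genes were -0.0314 at myclobutanil 500 ppm, hepatocyte markers -0.0444 at triadimefon 1800 ppm and -0.0316 between the propiconazole levels, male-biased genes 0.0599 between the myclobutanil levels and -0.0840 between myclobutanil and triadimefon at 500 ppm, where testis markers were 0.0472. Without arrays of high difference, phase II genes were -0.111, fatty acid synthesis -0.159, acute phase -0.380 and hepatocyte markers -0.386 at myclobutanil 500 ppm, acute phase -0.280 at 2000 ppm, fatty acid synthesis -0.140 and acute phase -0.270 at triadimefon 500 ppm, PPARα targets 0.294 at triadimefon 1800 ppm and 0.369 between its levels, male-biased genes 0.121 between the myclobutanil levels, and between myclobutanil and triadimefon at 500 ppm male-biased genes -0.140 and testis markers 0.0556. Between the propiconazole levels, leaving out 1 array gave interferon genes -0.0345 (without 2500 ppm replicate 1) to 0.108 and endothelial markers -0.0576 to 0.0251 (without replicate 4). With separate controls the correlation across probe sets was 0.733 for myclobutanil 2000 with propiconazole 2500 ppm, 0.676 for propiconazole with triadimefon at 500 ppm and -0.00266 for propiconazole 2500 with triadimefon 1800 ppm. Of the tests of named genes and lists with 1 array left out, 1000 and 3659 kept their side of the threshold (21 and 385 of these, not past it, changed sign), 216 and 121 lost the call and 7 and 112 gained one. The arrays without values and a pseudocount, which the scores do not allow, were not run. The number of arrays limits precision.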

Other observations

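The tests of the triadimefon levels against RNA integrity and against the scale of the values were chosen after the results had been seen, as was every use of the 3′–5′ difference as a covariate; the other tests here were chosen before.

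Other splits of the same arrays were tested as a measure of chance. The splits keep neither the animal number series nor RNA integrity together, so they bear on chance alone and not on these. The shares of splits were not adjusted over the comparisons. For propiconazole 2500 ppm against the controls 1 of 100 splits, the real one, gave as many as 79 probe sets (highest other 34). Chance alone is argued against there and for triadimefon 1800 against 500 ppm (1 of 100, real 7690, highest other 786). It is also argued against for the 10 cholesterol synthesis genes past the threshold at triadimefon 1800 ppm (1 of 100, highest other 3). For myclobutanil 2000 ppm 3 of 100 splits gave as many (real 20, highest other 981). For triadimefon 500 ppm 2 of 100 did (real 3, highest other 88). Chance is not excluded for these 2 comparisons, since other splits gave far more. Leaving out 1 array moved their counts from 0 to 3013 and from 0 to 4464. With the animal number series as a block the real counts were 18, 763, 2 and 1 for propiconazole 2500 ppm, the triadimefon levels, myclobutanil 2000 ppm and triadimefon 500 ppm. With the 3′–5′ difference as a covariate they were 25, 88, 2 and, in limma, 0 (1306 at unadjusted p under 0.05). For the 362 probe sets at triadimefon 1800 ppm chance is not excluded (5 of 100). The highest other split, 4911, set controls 1 to 3 and triadimefon replicate 1 against the rest, with a mean 3′–5′ difference of 0.858 against 1.66. This split follows RNA integrity and also the animal number series, since of the rest only control 4 is numbered below 3000. Which of these it reflects cannot be told apart. With the 3′–5′ difference as a covariate the real count was 604, and with the number series as a block it was 306. The 981 came from control 3 and myclobutanil 2000 ppm replicates 2 to 4 against the rest (0.607 against 1.30), and both splits point to a structure of the arrays beside the groups.

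Where limma gave 0 probe sets past the threshold, every split gives as many by construction, and the splits say nothing about chance. These comparisons were myclobutanil 500 ppm (100 of 100, 1281 at unadjusted p under 0.05, highest other 9495), propiconazole 500 ppm (100 of 100, 2866, highest other 868), the levels of myclobutanil (100 of 100, 3404, highest other 1538) and of propiconazole (35 of 35, 365, highest other 1). At 500 ppm they were myclobutanil against propiconazole (56 of 56, 1332, highest other 4511), myclobutanil against triadimefon (100 of 100, 5934, highest other 1) and propiconazole against triadimefon (56 of 56, 772, highest other 0). The 9495 and 4511 came from splits with mean 3′–5′ differences of 0.699 against 1.67 and 0.680 against 1.58.

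Many probe sets passed between triadimefon 1800 and 500 ppm. A wider scale of all values on the 1800 ppm arrays is argued against as the whole cause of the 7690, since 2386 of them passed in the same direction after quantile normalisation. The median absolute difference of the 7690 was then 0.1193, against 0.203 before, and its standard error 0.05045, against 0.0576. The wider scale stays open for the 5304 that did not pass, since the gap between the cre and bioB spikes was 1.264 times as wide at 1800 ppm (interval 1.02 to 1.57). A difference in RNA integrity stays open as well: with the 3′–5′ difference as a covariate 88 passed, the median absolute difference of the 7690 fell from 0.203 to 0.0875 and its standard error from 0.0576 to 0.0533, so the calls ended because the differences shrank. The animal number series stays open too. Replicates 2 to 4 at 1800 ppm are numbered above 3000 and all arrays at 500 ppm below, so series and level largely coincide. With the series as a block 763 passed, 683 of them among the 7690. The level of triadimefon itself stays open, and 319 of the 7690 also passed in the same direction against the controls.

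Cholesterol synthesis genes were higher at triadimefon 1800 ppm, with a median difference of 0.60. Loss of RNA integrity as the whole cause is argued against, since with the 3′–5′ difference as a covariate the median was 0.566 and 14 members passed. Among the controls, the 4 arrays of high 3′–5′ difference exceeded the 3 of low difference by a median of 0.160. The interval of that median, 0.0270 to 0.230, was drawn over the 20 genes and holds no spread between animals. Of those 4 arrays 3 are also numbered above 3000, so the controls do not separate RNA integrity from the number series. The animal number series as the whole cause is argued against by a median of 0.463 within the animals numbered above 3000 (n = 3 and 3), with 20 of 20 members positive. The interval of this median, 0.364 to 0.620, was likewise drawn over genes and not over animals. An effect of triadimefon may therefore account for the pattern, a hypothesis found and tested on the same data.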
